A study of Mus musculus with 14 samples.

How the data were processed

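RNA levels were measured in brain tissue and in the vastus lateralis, a part of the quadriceps muscle, of mice carrying a deletion of the Prader-Willi imprinting center (PWS-IC del) and of wild-type littermates. Each of the 14 samples was hybridised to its own Affymetrix Mouse Genome 430 2.0 array, a 1-colour array on which each probe set reports the level of a transcript. Per the labels, total RNA was extracted with Trizol and copied into biotin-labelled cRNA, and the mice were F1 hybrids of the FVB and B6 strains. The deposited values are intensity values on a linear scale, 1 per probe set and array. PLIER and the Affymetrix Expression Console made them, per the submitters' processing notes, which give no version of either. The settings of the summary step, any background correction and any normalization between arrays are not given in the sources used here. The values held 0 missing entries and 0 entries at or below 0, and 0 pairs of arrays held identical values.

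The sample titles call the arrays biological replicas and gave the group of every array. There were 4 wild-type and 3 PWS-IC del arrays for each tissue. The labels do not say whether brain and muscle samples with the same number came from the same mouse. The number of arrays limits the precision of every comparison, and an exact permutation test of 3 arrays against 4 cannot give a p below 0.0286.

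Of the 45101 probe sets, 64 were control probe sets and were left out of all tests. Gene symbols came from the platform annotation, which can be old. It gave 1 symbol to 34958 probe sets and several symbols to 932, and it did not list another 9160. Probe sets with several symbols name no gene here. By Entrez gene number, 34754 of the 1-symbol probe sets matched the RefSeq gene table of assembly GRCm38.p6, in which 0 symbols differed, and 204 did not match. No genome build is named for the array values, so the RefSeq table was used only for names, chromosomes and the order of neighbouring genes.

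Values were taken as log2(intensity + 16), and all differences are PWS-IC del minus wild-type on that scale, which understates the change of dim genes. Each of 18193 genes was represented by the 1-symbol probe set with the highest mean over the 14 arrays. In each tissue the genes below the 0.25 quantile of mean values were not tested, which left 13644 genes in brain and 13644 in muscle. Each tissue was fitted alone with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and the 2-sided moderated p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The difference between the genotype effects in brain and muscle was an interaction contrast over all 14 arrays and 14951 genes.

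Before the data were examined, 53 gene lists holding 1154 names were fixed, of which 1002 had a probe set and 11 were brought to a newer symbol. Lists with 3 or more tested members, 44 in brain and 36 in muscle, were tested with limma's camera at its preset correlation of 0.01, with adjustment over the lists of a tissue. Camera with an estimated correlation and fry were run beside it. Genes were also adjusted over their list alone. For the imprinted domain this adjustment covered every measured member, with no filter on low values. A list score is the mean over its tested members of each array's deviation from the mean of the tissue.

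The rule for named genes was also fixed before the data were examined. It took, per tissue, up to 10 rises and 10 falls of the largest size among genes past the threshold, all measured genes of the imprinted domain, and up to 4 members with the smallest p of every list described. Where fewer than 10 genes passed in a tissue, the 10 with the smallest p were named. Genes outside this rule are said to be chosen after their values were seen.

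Alternatives set before the data were seen covered the pseudocount, quantile normalization, median centring, the filter on low values, the choice or mean of probe sets, an intensity trend, array quality weights, leaving out sex-linked genes, a threshold of 0.1, a joint fit of all arrays, the replicate number as a block, the correlation within lists and leaving out each array in turn. Fits without pairs of brain arrays and with marker means as covariates were added after seeing the data.

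The fits were tested on simulated data in which 200 genes were changed by known amounts. In the brain comparison, run on 13644 genes, 24% of genes changed by 0.5 log2 units were recovered, 86% of those changed by 1, and 100% of those changed by 2 or 4, with 14 false calls. The muscle comparison on 13644 genes recovered 46%, 80%, 96% and 100% at these sizes, with 9 false calls. For the interaction on 14951 genes the shares were 12%, 72%, 98% and 100%, with 9 false calls. In each tissue a list of 69 genes shifted by 0.5 was found, with 0 other lists called. The simulated noise was independent between genes, whereas the correlation estimated within this list was 0.798 in brain and 0.226 in muscle. The run therefore does not show how often lists of correlated genes are called by chance.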

Results

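Prader-Willi syndrome arises from loss of paternally expressed genes of an imprinted domain, which lies on chromosome 7 in the mouse, and the imprinting center is the element that controls the domain's parent-specific expression. The series asked which genes differ in expression in brain and skeletal muscle of mice with a deletion of this center, with mitochondrial function named in its title. The 14 arrays comprised 4 wild-type and 3 PWS-IC del arrays of brain and the same numbers of muscle. Median intensity lay between 142.0 and 170.1 in the brain arrays and between 88.7 and 96.4 in the muscle arrays. Brain arrays correlated with each other at 0.944 to 0.991 and muscle arrays at 0.974 to 0.993. Over 22 array measures the smallest exact permutation p was 0.0857, where 4 and 3 arrays allow none below 0.0286, so this test says little about whether the arrays differ between genotypes. Xist, the RNA of the inactive X chromosome, was at 10.55 to 12.21 log2 in all 14 arrays, while the Y-linked Eif2s3y was at 4.23 to 5.20.

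The genes of the targeted domain were examined first. In brain, Snrpn, which encodes a small nuclear ribonucleoprotein subunit, fell by 4.87 ± 0.29 (SE) on the log2 scale, from 10.52 ± 0.16 (SD, n = 4) to 5.65 ± 0.75 (SD, n = 3), with an adjusted p of 2.22e-04. A further 6 probe sets are annotated to several symbols, Snrpn among them, and so name no gene here. They ranged from -8.86 to -1.98, 5 of them lower past the threshold over all probe sets. Ndn, which encodes the MAGE-family protein necdin, fell by 4.13 ± 0.26 (adjusted p = 2.77e-04). Snhg14, the long host transcript of small nucleolar RNAs that runs antisense across Ube3a, fell by 3.63 ± 0.21 (adjusted p = 1.88e-04). Magel2, another MAGE-family gene, fell by 1.95 ± 0.25 (adjusted p = 0.0482), a call lost when any 1 of the 7 arrays was left out. Mkrn3, a zinc-finger gene of the domain, was among the dim genes not tested over all genes. Its difference was -1.54 with an adjusted p of 6.67e-07 over the list alone.

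Of the 8 measured paternally expressed genes in brain, 4 were lower over all genes tested and 5 were lower adjusted over the list alone. The remaining 3 were Peg12 at -0.19, Ipw at -0.09 and Gm26504, which RefSeq gives as the Snord116 locus, at -0.09. Wild-type brain had Peg12 at 4.53 and Gm26504 at 5.28, which leaves limited room to show a fall, and Ipw at 8.96. As a list the paternally expressed genes fell, with a median of -3.63 over 5 tested members (camera adjusted p = 7.52e-16). The call held with an adjusted p = 0.0197 with an estimated correlation. A230006K03Rik, a transcript that RefSeq places beside Snrpn, fell by 3.97 ± 0.20 (SE), and the next one, B230209E15Rik, fell by 3.27 ± 0.26. Gm31445, which has no position here, fell by 3.33 ± 0.32. Probe sets of a gene did not all move alike. The 8 probe sets of Ndn ranged from -4.83 to 0.13 in brain, 7 of them lower past the threshold over all probe sets.

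Next to these lie the maternally expressed genes. Ube3a, which encodes a ubiquitin ligase, was 0.76 ± 0.14 (SE) higher in mutant brain, with 11.58 ± 0.23 (SD, n = 4) in wild-type and 12.35 ± 0.11 (SD, n = 3) in mutants. It did not pass over all genes (adjusted p = 0.437), and passed with 8.69e-04 adjusted over the list alone. Of its 6 probe sets 5 were higher in mutants, from 0.06 to 0.99, and the other was at -0.40. Atp10a, which encodes a phospholipid flippase, was at -0.42 (adjusted p = 0.566), and 1 of 2 members of this list was higher adjusted over the list alone. C230091D08Rik, a name RefSeq lists as a synonym of Snhg14, rose by 0.76 ± 0.10 (adjusted p = 0.0445) while the probe set annotated as Snhg14 itself fell. That rise was past the threshold in 0 of the 7 fits that each left out 1 array.

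**Figure D1:**
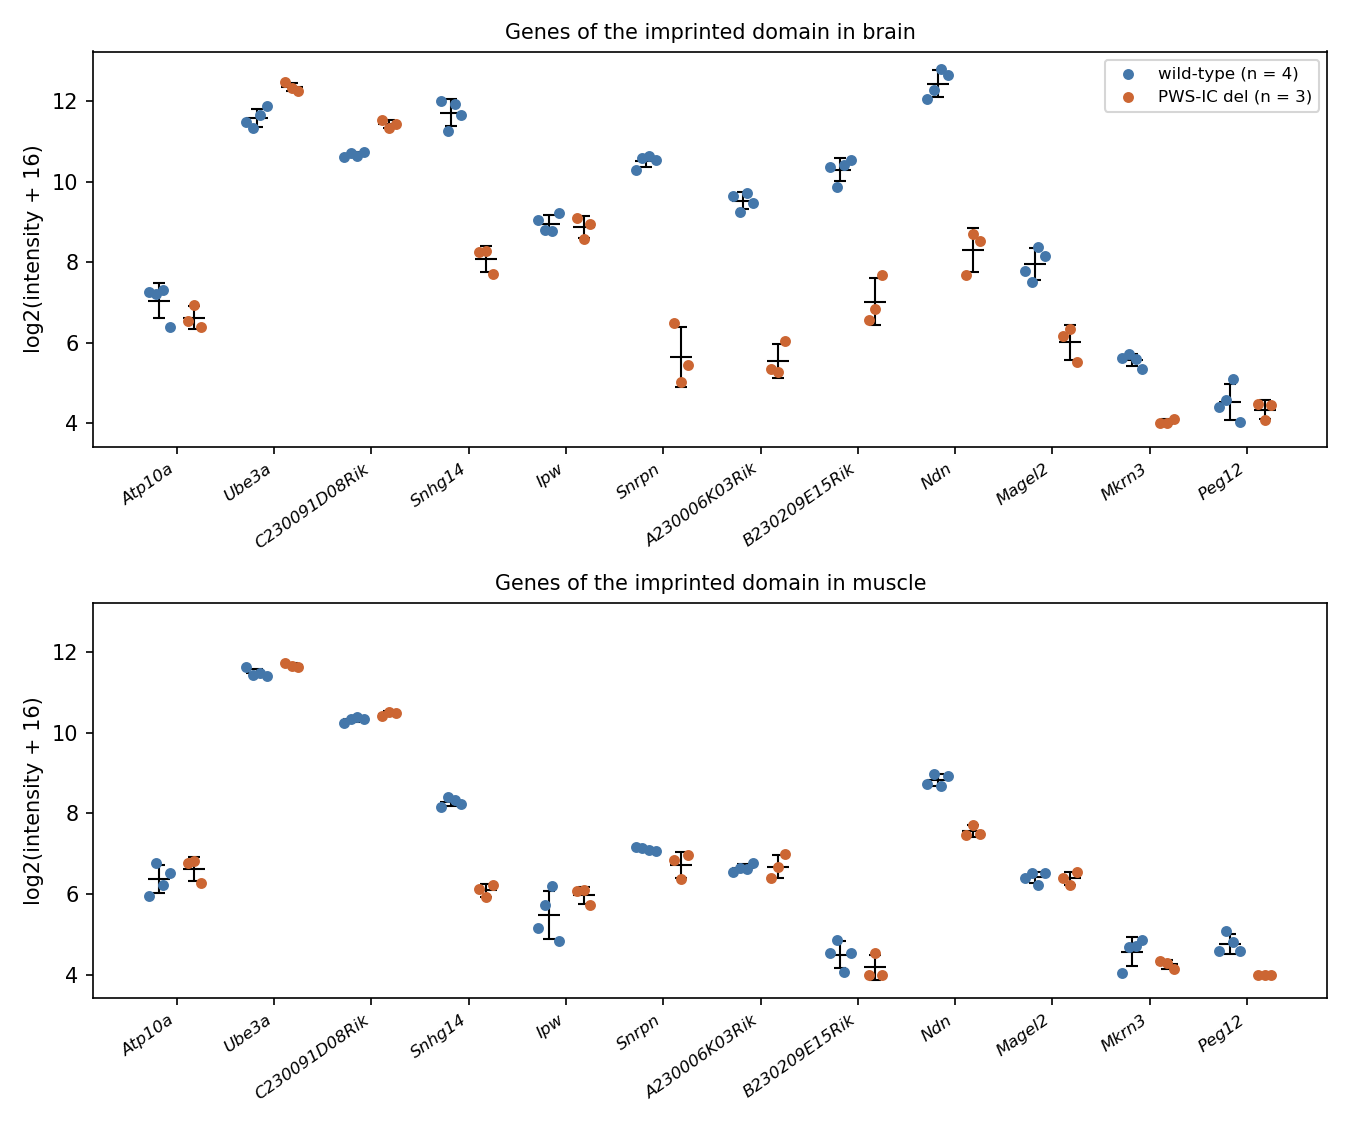
Each point is 1 array, with log2(intensity + 16) on the vertical axis for genes of the imprinted domain in brain (top) and muscle (bottom), and bars give the mean and SD of 4 wild-type and 3 PWS-IC del arrays. In brain, Snrpn averages 10.52 in wild-type and 5.65 in mutants, and in muscle Snhg14 averages 8.29 and 6.09.

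In muscle, 2 of the paternally expressed genes passed over all genes tested. Snhg14 fell by 2.20 ± 0.10 (SE), from 8.29 ± 0.11 (SD, n = 4) to 6.09 ± 0.16 (SD, n = 3), with an adjusted p of 1.53e-04. Ndn fell by 1.27 ± 0.11 (adjusted p = 0.00439) on the probe set chosen for it, and its 8 probe sets ranged from -3.22 to -0.32. Most of them fell further than the chosen one, such as 1 from 8.96 to 5.82. Snrpn was at -0.39 ± 0.14 with an adjusted p of 0.325 and passed only over the list alone (0.045). The 6 probe sets that carry its symbol beside another ranged from -5.12 to -0.04 in muscle, 4 of them lower past the threshold over all probe sets. Of 8 measured members, 4 were lower adjusted over the list alone, including Peg12 at -0.76, whose mutant values lay at the floor of the scale. Magel2 was at -0.03, Mkrn3 at -0.32, Ipw at 0.49 and Gm26504 at 0.08. Their wild-type muscle levels were low, at 6.42, 4.57, 5.48 and 5.15 in that order, which leaves limited room to show a fall. Magel2 was at 6.01 in mutant brain. Ube3a was at 0.18 (adjusted p = 0.423) and Atp10a at 0.25 (adjusted p = 0.652). The list fell, with a median of -0.83 over 4 tested members (camera adjusted p = 3.95e-06), with an adjusted p = 0.330 with an estimated correlation.

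In brain, 1 gene with a position outside the domain passed, Gm5802. Of 13644 genes 9 passed, 1 higher and 8 lower, against 1119 at an unadjusted p under 0.05, where independent genes would give 682 by chance. Genes are not independent, and other splits of the brain arrays gave 27 to 3973, so this excess does not show an effect of genotype. Of the 9, 6 were on chromosome 7 among 7 with a position (Fisher's exact adjusted p = 2.73e-05). These 6 were genes of the targeted domain, so the test says nothing about the rest of the chromosome. Within 100 annotated genes of the domain 0 of 42 tested genes passed, and 0 of 1000 on the rest of chromosome 7. C230091D08Rik and Gm31445 also passed and have no position here. Gm5802 fell by 2.33 ± 0.10 (adjusted p = 5.25e-05). RefSeq places it on chromosome 14, and its probe set is of a type (x_at) whose probes can match several transcripts. The 10th gene by p, Zscan5b, a zinc-finger gene, was at -0.71 ± 0.10 and did not pass (adjusted p = 0.114). Groups did not overlap for 8.66% of genes, where chance gives 5.71%.

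In brain 9 lists outside the domain passed camera at its preset correlation. With an estimated correlation 0 of them passed, and without wild-type 1 and 2, a choice made after seeing the data, 2 did. All 69 genes of the mitochondrial ribosome had positive differences, with a median of 0.24 (camera adjusted p = 9.43e-13, and adjusted p = 0.881 with an estimated correlation), among them Mrpl1 at 0.47, Mrps18c at 0.39, Mrps31 at 0.34 and Mrpl33 at 0.31. Subunits of respiratory complex I, the NADH dehydrogenase, were positive in 32 of 33 with a median of 0.11 (adjusted p = 0.00476, and adjusted p = 0.881 with an estimated correlation), including Ndufa6 at 0.34, Ndufs5 at 0.28, Ndufs4 at 0.26 and Ndufa5 at 0.23. Fatty acid oxidation genes were positive in 22 of 24 with a median of 0.27 (adjusted p = 0.00544, and adjusted p = 0.881 with an estimated correlation), with the isomerase Eci1 at 0.38, the kinase Pdk4, which restrains pyruvate oxidation, at 0.37, the carnitine carrier Slc25a20 at 0.33 and the fatty acid binding protein Fabp3 at 0.28. Heat shock genes were positive in 14 of 14 with a median of 0.19 (adjusted p = 0.00475, and adjusted p = 0.881 with an estimated correlation), with the chaperones Hspa1a at 0.69, Hspa1b at 0.59, Dnajb1 at 0.39 and Dnajb4 at 0.36. The unfolded protein response, the reaction to misfolded protein in the endoplasmic reticulum, was positive in 19 of 24 with a median of 0.16 (adjusted p = 0.00558, and adjusted p = 0.881 with an estimated correlation), with Manf at 0.55, Sdf2l1 at 0.53, Creld2 at 0.48 and the transcription factor Xbp1 at 0.44. Cytosolic ribosomal proteins were positive in 31 of 34 with a median of 0.12 (adjusted p = 0.0142, and adjusted p = 0.881 with an estimated correlation), including Rpl14 at 0.46, Rpl37 at 0.26, Rpl35 at 0.21 and Rpl22 at 0.19. Complexes II, III, IV and V had medians of 0.13, 0.12, 0.06 and 0.06 and did not pass, and the mitochondrially encoded ND5 was at -0.06.

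Genes of the endothelium list were negative in mutant brain in 13 of 13 with a median of -0.26 (camera adjusted p = 1.43e-08, and adjusted p = 0.881 with an estimated correlation). Among them were the transporter Slco1a4 at -0.63, the VEGF receptors Flt1 at -0.78 and Kdr at -0.44, and Eng at -0.39. Markers of striatal neurons were negative in 11 of 11 with a median of -0.56 (adjusted p = 3.34e-04, and adjusted p = 0.881 with an estimated correlation), including the dopamine receptor Drd2 at -0.87, the opioid precursor Penk at -0.66, Pde1b at -0.56 and Adcy5 at -0.54. Potassium and calcium channel genes had 13 of 20 negative, with a median of -0.08 (adjusted p = 0.0103, and adjusted p = 0.881 with an estimated correlation) and Cacna1b at -0.58, Cacna1c at -0.38, Hcn2 at -0.27 and Kcna4 at -0.26. In these 9 lists outside the domain 0 members passed over all genes and 0 adjusted over the list alone.

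Markers of other tissue moved among the same brain arrays. Wild-type 1 and 2 stood apart on the first principal component (36.5 and 22.6, others -25.9 to 7.15), which held 51.9% of the variance. Their mitochondrial ribosome scores were -0.33 and -0.14, against -0.07 and 0.12 in wild-type 3 and 4 and 0.08 to 0.24 in mutants. Their striatal scores were 1.08 and 0.56, with the other arrays at -0.95 to 0.24. Ttr, the choroid plexus transcript for transthyretin, was at 11.84 and 11.91 in them and higher in the others, up to 13.74. Skeletal muscle transcripts were high in wild-type 1 and 3, with Ckm at 10.38 and 9.61 against 6.38 to 7.25 elsewhere and Myh4 at 10.78 in wild-type 1 against 5.77 to 6.82 in the arrays other than these. Wild-type 3 alone carried pituitary hormone transcripts, with Prl at 10.45 against 5.84 to 6.38. The Purkinje cell gene Pcp2 was at 16.76 in PWS-IC del 2 and 13.03 in wild-type 3, against 8.19 to 8.79 in the others. Cerebellar markers had a median of 0.49 (camera adjusted p = 0.116).

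**Figure D2:**
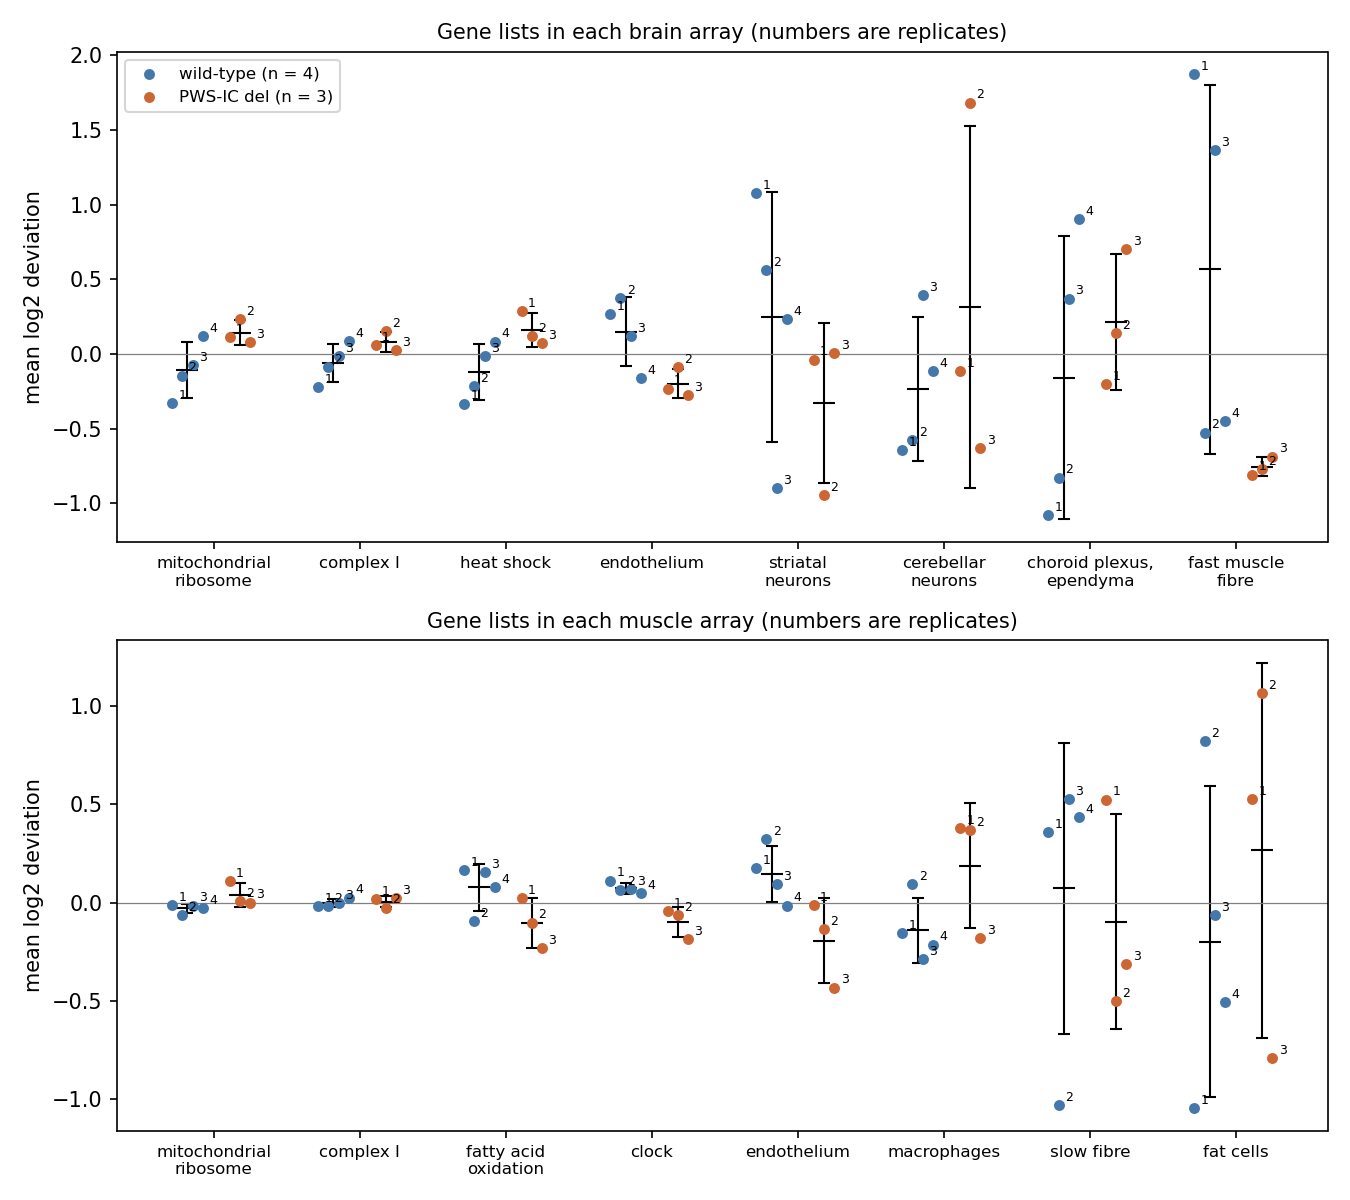
Each point is 1 array, numbered by replicate, and the vertical axis gives the mean log2 deviation of a gene list from the tissue mean in brain (top) and muscle (bottom), with bars for the mean and SD of 4 wild-type and 3 PWS-IC del arrays. Brain wild-type 1 is lowest for the mitochondrial ribosome (-0.33) and highest for striatal neurons (1.08), and PWS-IC del 2 is highest for cerebellar neurons (1.68).

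In muscle, genes outside the domain passed the threshold as well, though chance is not excluded for their number. Of 13644 genes 16 passed, 2 higher and 14 lower, with 1629 at an unadjusted p under 0.05, where independent genes would give 682 by chance. Other splits of the muscle arrays gave 124 to 2366, so this excess does not show an effect of genotype either. The count and its balance depend on the processing, with 13 higher and 33 lower after quantile normalization. Median centring gave 8 and 17, array weights gave 1073 and 788, and the replicate block gave 0 and 2. Cyfip2, whose product is part of an actin-regulating complex, fell by 1.90 ± 0.17 (SE), from 8.38 ± 0.34 (SD, n = 4) to 6.48 ± 0.07 (SD, n = 3), with an adjusted p of 0.00593. Acot1, a cytosolic acyl-CoA thioesterase, fell by 1.47 ± 0.19 (adjusted p = 0.0356). Ddah1, which degrades an inhibitor of nitric oxide synthase, fell by 1.16 ± 0.09 (adjusted p = 0.00439). Esrrg, a nuclear receptor that drives oxidative muscle genes, fell by 0.94 ± 0.12 (adjusted p = 0.0356). Also lower were Gm5802 at -1.55 ± 0.08, the Wnt antagonist Frzb at -0.95 ± 0.12, the collagen gene Col24a1 at -0.91 ± 0.12 and the scaffold gene Homer2 at -0.89 ± 0.09. Kcnab1, a potassium channel subunit, rose by 1.21 ± 0.15 (adjusted p = 0.0356) and Kazald1, a secreted protein gene, rose by 1.12 ± 0.09 (adjusted p = 0.00439). The other 4 falls, named after their values were seen, were Rcan2 at -0.86, Ptger4 at -0.81, St3gal5 at -0.79 and As3mt at -0.66. Leaving out 1 array at a time gave 6 to 26 genes, 26 without wild-type 2 and 6 without wild-type 3, wild-type 4 or PWS-IC del 2. Snhg14, Gm5802, Ndn, Cyfip2, Ddah1 and Kazald1 passed in all 7 of these fits, Homer2 in 3, Acot1, Esrrg, Col24a1 and Kcnab1 in 1 each and Frzb in 0.

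**Figure D3:**
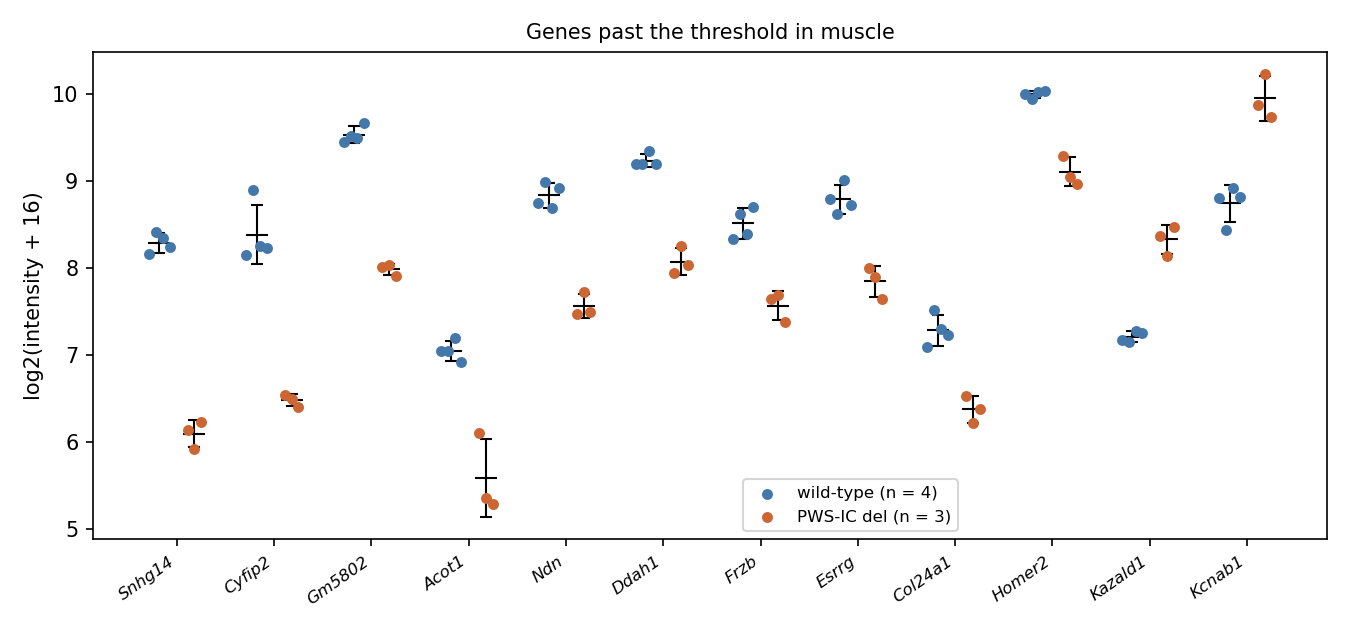
Each point is 1 muscle array, with log2(intensity + 16) on the vertical axis for the named genes past the threshold, and bars give the mean and SD of 4 wild-type and 3 PWS-IC del arrays. Cyfip2 averages 8.38 in wild-type and 6.48 in mutants, and Kazald1 averages 7.21 and 8.33.

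Most fatty acid oxidation and circadian clock genes had negative differences in mutant muscle. Of 24 fatty acid oxidation genes 20 were negative, with a median of -0.18 (camera adjusted p = 4.62e-05), among them the trifunctional protein subunit Hadha at -0.40, the isomerase Eci2 at -0.34, the dehydrogenase Acadl at -0.29 and Fabp3 at -0.76. None of the 24 passed over all genes or adjusted over the list alone, and the list had an adjusted p = 0.972 with an estimated correlation. The 16 clock genes had a median of -0.17 (camera adjusted p = 0.00131), with 1 higher and 6 lower adjusted over the list alone and 0 over all genes. This list had an adjusted p = 0.330 with an estimated correlation, and fry gave 0.0398. The lower genes included the output factor Dbp at -0.94, the repressor Ciart at -0.76, Bhlhe40 at -0.48 and the period gene Per2 at -0.40. Immediate early genes, transcribed within minutes of a stimulus, were negative in 13 of 17 with a median of -0.27 (adjusted p = 0.00155), with 0 passing over all genes and 3 lower adjusted over the list alone. Dusp1 was at -0.78, Ccn1 at -0.51, Egr1 at -0.47 and Per1, which both lists hold, at -0.45, and the list had an adjusted p = 0.972 with an estimated correlation.

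**Figure D4:**
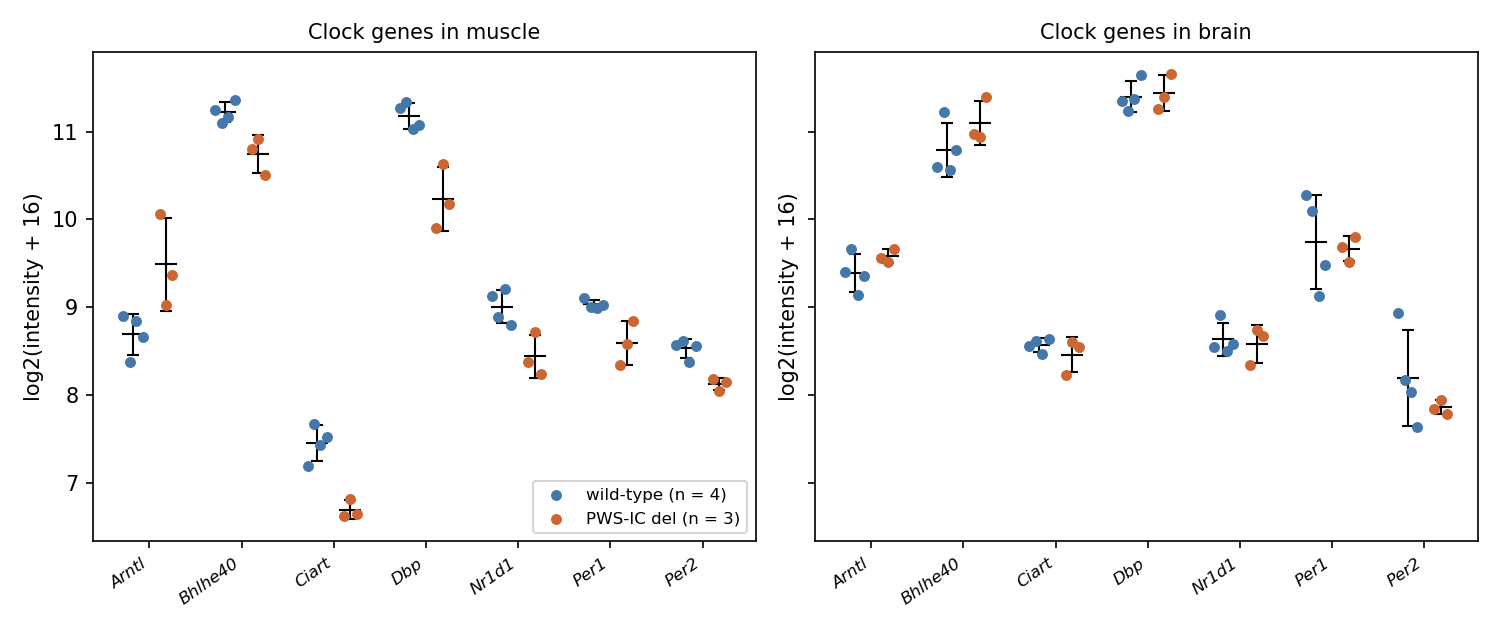
Each point is 1 array, with log2(intensity + 16) on the vertical axis for 7 clock genes in muscle (left) and brain (right), and bars give the mean and SD of 4 wild-type and 3 PWS-IC del arrays. In muscle Dbp averages 11.18 in wild-type and 10.24 in mutants, and in brain 11.40 and 11.44.

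Some lists of cell type markers passed camera in muscle at its preset correlation and not with an estimated one. Genes of the endothelium list, not all of them limited to endothelial cells, were negative in 14 of 14 with a median of -0.31 (camera adjusted p = 2.70e-07). The list had an adjusted p = 0.904 with an estimated correlation. Rgs5 at -0.51, Vwf at -0.53, Flt1 at -0.54 and Egfl7 at -0.55 were the 4 that were lower adjusted over the list alone. Macrophage genes were positive in 18 of 19 with a median of 0.38 (adjusted p = 4.97e-05, and adjusted p = 0.972 with an estimated correlation), with the protease Ctss at 0.63, Fcgr3 at 0.65, Lyz2 at 0.44 and Cd68 at 0.39, and 1 was higher adjusted over the list alone. Matrix genes were positive in 18 of 24 with a median of 0.28 (adjusted p = 0.00448, and adjusted p = 0.972 with an estimated correlation), with the collagen crosslinker Lox at 0.55, the tendon gene Tnmd at 0.66, Thbs4 at 0.40 and Bgn at 0.25, and 0 passed adjusted over the list alone. Slow fibre genes had 9 of 16 negative with a median of -0.12 (adjusted p = 0.0215, and adjusted p = 0.972 with an estimated correlation), with the calcium store protein Casq2 at -1.03, the calcium pump inhibitor Pln at -0.39, Mb at -0.26 and Fhl2 at -0.25, and 2 were lower adjusted over the list alone. In none of these lists did a member pass over all genes. Slow fibre scores were -1.03 in wild-type 2 and 0.36 to 0.53 in the other wild-type arrays, and -0.50 to 0.53 in mutants. Fat cell markers were at a median of 0.30 (camera adjusted p = 0.204), with scores of -1.05 to 0.82 in wild-type and -0.80 to 1.07 in mutants.

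A further 4 lists passed camera upward in muscle at the preset correlation and not with an estimated one, and 0 of their genes passed over all genes. Antioxidant genes were positive in 22 of 25 with a median of 0.11 (camera adjusted p = 0.00196, and adjusted p = 0.972 with an estimated correlation), with the metallothioneins Mt2 at 0.47 and Mt1 at 0.41, Gpx1 at 0.41 and Hmox1 at 0.22, and 1 higher adjusted over the list alone. The mitochondrial ribosome was positive in 51 of 69 with a median of 0.08 (adjusted p = 0.00237, and adjusted p = 0.972 with an estimated correlation), including Mrpl50 at 0.29, Mrps12 at 0.26, Mrpl13 at 0.23 and Mrps33 at 0.18. Cell cycle genes were positive in 13 of 15 with a median of 0.13 (adjusted p = 0.00247, and adjusted p = 0.407 with an estimated correlation), and Pcna at 0.38, Aurka at 0.36, Tk1 at 0.31 and Mcm3 at 0.29 were the 4 higher adjusted over the list alone. Interferon response genes were positive in 16 of 19 with a median of 0.17 (adjusted p = 0.0449, and adjusted p = 0.972 with an estimated correlation), with Ifi27l2a at 1.83, Bst2 at 0.39, Irf9 at 0.32 and Mx1 at -0.19. Respiratory complexes I to V had medians of 0.01, 0.01, -0.01, 0.02 and 0.02 and did not pass, and ND5, the sole mitochondrially encoded gene tested, was at -0.18 with an adjusted p of 0.339.

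The effects in brain and muscle were then compared directly. The interaction passed for 12 of 14951 genes, with 983 at an unadjusted p under 0.05. Leaving out 1 array at a time gave 7 to 16 genes, 7 without brain wild-type 1, brain PWS-IC del 1 or muscle PWS-IC del 2, and the replicate block gave 2. On the probe set chosen for each gene, the brain effect minus the muscle effect was -4.48 ± 0.36 (SE) for Snrpn, -4.01 ± 0.26 for A230006K03Rik, -2.86 ± 0.31 for Ndn and -1.92 ± 0.30 for Magel2. These contrasts rest on levels that differ between the tissues, wild-type muscle having A230006K03Rik at 6.64 and Magel2 at 6.42, where wild-type brain had 9.53 and 7.96. Mutant brain had A230006K03Rik at 5.56 and Magel2 at 6.01, so their muscle levels may be background and their contrasts may not compare falls. The same holds for the probe set chosen for Snrpn. It was at 7.12 in wild-type and 6.73 in mutant muscle, against 5.65 in mutant brain. Another probe set of Ndn was at -4.35 in brain and -3.14 in muscle. Of those that carry the symbol of Snrpn beside another, 1 was at -2.89 and -2.01, so the size of the Ndn and Snrpn contrasts depends on the probe set. A further such probe set was at -8.86 and -5.12, with mutant means at the floor of the scale (4.24 in brain, 4.09 in muscle). Its differences are limited by its wild-type levels of 13.10 and 9.21. Gm5802 at -0.78 had the same sign. Gm31445 and B230209E15Rik also passed, but were near the floor of the scale in wild-type muscle (4.65 and 4.50), so their contrasts do not compare falls. The falls of Cyfip2, Acot1 and Ddah1 in muscle differed from brain by 1.83 ± 0.21, 1.88 ± 0.27 and 1.10 ± 0.14. The rise of Kcnab1 in muscle gave -1.20 ± 0.19, and Cilp, a matrix protein gene, gave -0.89 ± 0.14. The effects on Snhg14 (adjusted p = 0.0571), Ube3a (0.482) and Dbp (0.269) were not shown to differ between tissues. Over 12337 genes tested in both tissues, the effects correlated across genes, which are not independent replicates, with Pearson r = 0.276 (0.155 without brain wild-type 1 and 2) and Spearman rho = 0.324, and 62.6% had the same sign. Gm5802, Ndn and Snhg14 were lower in both, 3 shared among 6 and 13 lower genes where independent lists give 0.00632 (Fisher's exact p = 1.82e-08, 2-sided), and 0 genes were higher in both. Ndn and Snhg14 belong to the domain that the deletion targets in both tissues, and Gm5802 rests on an x_at probe set. This overlap therefore says nothing about shared effects outside the domain.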

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

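The counts over other splits of the arrays were planned for the numbers of genes and lists, the correlation and the overlap. Chosen only after the result was seen were the tests that left out brain wild-type 1 and 2 or wild-type 3 and PWS-IC del 2, those on the flank of the domain, and the tests of explanations for the clock genes with their counts over splits.

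Single arrays lay far from the other wild-type arrays in 5 of 143 groups checked, where chance gives about 1 in 20. The gap over the range was 0.898 for Atp10a in brain wild-type 4 (6.40, others 7.22 to 7.31). It was 0.852 for Cyfip2 in muscle wild-type 2 (8.89, others 8.15 to 8.26), in the direction away from the mutants. For Ddah1 in muscle wild-type 3 it was 0.956 (9.34, others 9.19 to 9.20), and for Eci2 in muscle wild-type 1 it was 0.874 (11.51, others 11.30 to 11.33). The slow fibre score of muscle wild-type 2 gave 0.892 (-1.03, others 0.36 to 0.53).

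The interaction contrast of limma gave 12 genes whose effect in brain differed from that in muscle. It was -4.01 for A230006K03Rik, -4.48 for Snrpn, -2.86 for Ndn, -3.42 for Gm31445, -2.95 for B230209E15Rik, -1.92 for Magel2 and -0.78 for Gm5802, which are lower in mutant brain. The size depends on the probe set. Another of Ndn was at -4.35 in brain and -3.14 in muscle, and 1 that carries the symbol of Snrpn beside another was at -2.89 and -2.01. A further such probe set was at -8.86 and -5.12, with mutant means at the floor of the scale (4.24 and 4.09). Its differences are limited by its wild-type levels. Magel2 was at 6.42 in wild-type muscle and 7.96 in wild-type brain, B230209E15Rik was at 4.50 and 10.29 and Gm31445 at 4.65 and 8.08, so B230209E15Rik and Gm31445 had little room to fall in muscle. Magel2 was at 6.01 and A230006K03Rik at 5.56 in mutant brain, where wild-type muscle had 6.42 and 6.64. Their muscle levels may be background, and their contrasts may not compare falls. The same holds for the probe set chosen for Snrpn, at 5.65 in mutant brain, 7.12 in wild-type muscle and 6.73 in mutant muscle. Cyfip2 gave 1.83, Ddah1 1.10, Acot1 1.88, Kcnab1 -1.20 and Cilp -0.89, and of these Cyfip2, Ddah1, Acot1 and Kcnab1 passed in muscle and not in brain.

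Probe sets that name no gene here held further signal. In brain 5 probe sets with several symbols were lower past the threshold (-8.86 to -2.35), as were 3 with no listed symbol (-3.95 to -2.42). In muscle 4 with several symbols were lower (-5.12 to -0.85), and of 9 with no listed symbol 7 were lower and 2 higher (-1.19 to 1.19).

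Other splits of the arrays into 4 and 3 show how far the counts could come from the arrays alone. In brain 2 of 35 splits called as many genes as the genotypes did (9), and the other of them, wild-type 1 and 2 with PWS-IC del 3, called 1354, which points to a structure among the arrays. In muscle 2 of 35 splits called as many as the genotypes (16), the other, wild-type 2 with PWS-IC del 1 and 2, calling 584. For the interaction 6 of 100 drawn splits called as many as 12, with up to 377. For gene lists, 23 of 35 splits in brain called as many as 10 and up to 23, and 5 of 35 in muscle called as many as 12 and up to 14. Chance is therefore not excluded for these 5 counts. For the correlation of effects between tissues, 2 of 100 splits reached it with all 14 arrays (0.276, highest other 0.285). That is under the 5 of 100 set in advance, which argues against chance without excluding it. Without brain wild-type 1 and 2, 16 of 100 splits reached the correlation found then (0.155, highest other 0.293), so chance is not excluded there either. The 3 genes lower in both tissues were reached by 1 of 100, with 0 as the highest other, but 0 of the other draws called any gene in both tissues, so this count decides nothing. Values of Snrpn, Ndn, Snhg14 and Magel2 did not overlap between genotypes in brain. These genes had already passed the threshold, and 8.66% of all tested brain genes did not overlap, so this does not bear on chance.

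The shifts of brain gene lists outside the domain may follow wild-type 1 and 2. Without these arrays 2 of the 9 lists stayed past the threshold, while leaving out any other pair of wild-type arrays kept 7 to 9. Uneven brain regions in wild-type 3 and PWS-IC del 2, the arrays rich in cerebellar transcripts, are argued against, since 9 of the 9 lists remained without them. An effect of the deletion on mitochondrial genes in brain stays open, because 4 wild-type arrays cannot settle which of them are typical.

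The higher Ube3a and C230091D08Rik in mutant brain are a candidate effect of the loss of Snhg14, whose transcript runs antisense to Ube3a, and that remains a hypothesis. The rise was not carried by wild-type 1 and 2 alone, since the smaller difference, that of Ube3a, was 0.59 without them (limma adjusted p = 0.643). The groups did not overlap without these arrays, but this was fixed in advance, since they did not overlap with all arrays. A shift of the whole flank of the domain is argued against by the upper quartile of 0.18 over 15 flanking genes (median 0.11, range -0.39 to 0.29). The call of C230091D08Rik was lost in each fit that left out 1 array, the strand its probe set reads was not analysed here, and RefSeq gives its name to Snhg14, so which transcript rose stays open.

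Of the 16 clock genes tested in muscle 7 passed over the list alone and 0 over all genes, with Arntl at 0.80 (adjusted p = 0.0193 over the list alone) and Nr1d1, which represses it, at -0.57. The genotype split alone among 35 gave 7 clock genes past the threshold over the list alone, the highest other giving 1, but this list was singled out after its result was seen. In 9 of 35 splits some list outside the domain had as many members past the threshold over the list alone, with up to 18, so chance is not excluded. Fat in the samples is argued against, since the median size of the 7 differences was 0.57 without and 0.60 with fat cell markers as a covariate. Muscle taken at another time of day in the mutants cannot be told apart from an effect of the deletion. The median in brain, turned to the direction of muscle, was 0.078, but the labels neither tie the tissues to the same mice nor give a time of collection.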

How the results depend on the processing

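The fits without pairs of brain arrays and with marker covariates were chosen after seeing the data, and all other alternatives were planned. The cause of the changes listed was not tested, except that fewer arrays or another number of genes enter some fits by construction. In brain 9 genes became 24 over 33777 probe sets, 3 with the replicate block and 5 without wild-type 1 and 3, and 6 to 7 when 1 array was left out. The split into higher and lower was 1 and 8, 0 and 7 with quantile normalization and 0 and 8 with median centring. Of 10 brain lists 1 held with an estimated correlation, 16 passed with cerebellar markers as a covariate, and 9 to 14 passed when 1 array was left out. Without wild-type 1 and 2 11 passed, of which 3 were shared. The 16 genes of muscle became 29 with pseudocount 64, 46 with quantile normalization (13 higher, 33 lower), 25 with median centring (8 and 17), 8 with no filter, 29 above the median, 48 over all probe sets, 59 with an intensity trend and 1861 with array weights (1073 and 788). They became 84 at a threshold of 0.1, 39 in the joint fit, 60 with fat cell markers as a covariate, and 6 to 26 when 1 array was left out (8 without wild-type 1, 26 without wild-type 2, 6 without wild-type 3, wild-type 4 or PWS-IC del 2). Of 12 muscle lists 0 held with an estimated correlation and 8 to 13 passed when 1 array was left out, while fry called 2. The 12 genes of the interaction became 6 with pseudocount 1, 27 over all probe sets, 73 with array weights, 20 at a threshold of 0.1, 4 without brain wild-type 1 and 3, 7 without brain wild-type 3 and PWS-IC del 2, and 7 to 16 when 1 array was left out. The correlation between tissues was 0.155 without brain wild-type 1 and 2, and the shared falls numbered 2 to 3 in the fits for which they were recounted.

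The replicate numbers were checked for pairing. Deviations of same-numbered wild-type and mutant arrays correlated at -0.06, -0.35 and -0.52 in brain and at 0.08, 0.52 and 0.01 in muscle. Muscle PWS-IC del 1 and 2 matched best with their own number, and the other mutant arrays did not. So few arrays cannot settle whether a shared number marks a pairing. With the replicate block 3 genes passed in brain, 2 in muscle and 2 in the interaction.

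Small differences that did not pass changed sign. ND5 in brain was 0.018 with median centring and 0.010 without wild-type 1 and 3. Ipw in brain was 0.088 with array weights, 0.0016 without wild-type 3 and PWS-IC del 2, 0.0053 with the cerebellar covariate and -0.20 to 0.059 when 1 array was left out. Magel2 in muscle was 0.015 with quantile normalization, 0.0065 with median centring, 0.0081 with the replicate block, 0.0013 with the fat covariate and -0.11 to 0.053 when 1 array was left out. Of 1300 refits of named genes in brain 1249 were counted as unchanged, 39 lost the call and 4 gained one. In muscle 1287 of 1403 were unchanged, 56 lost it and 50 gained one. Direction changed in 6 and 7. Unchanged meant the same direction and side of the threshold, or for untested genes a shift within the spread of the arrays. Most named genes had no call to lose, so these totals do not show how stable the calls were. In brain C230091D08Rik lost its call in 18 of 25 refits and Magel2 in 15 of 24, while Ndn and Gm5802 lost it in 0 of 25. In muscle Frzb lost it in 11 of 22, while Gm5802 lost it in 0 of 22. Genes near the floor, such as Mkrn3 and Peg12, have differences limited by signal over background.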

Other observations

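No test in this part bears on a hypothesis, and the genes named here were chosen after their values were seen. Regulators of mitochondrial number and shape did not shift as a list in mutant muscle, with a median of -0.03 over 23 genes (camera adjusted p = 0.464). Ppargc1a, the coactivator that drives mitochondrial biogenesis, was the 1 member lower adjusted over the list alone (0.0241), at -0.35 ± 0.07 (SE), and it did not pass over all genes (adjusted p = 0.118). Esrrg, one of its partner receptors, fell by 0.94. Among the genes beside the imprinted domain Herc2, a giant ubiquitin ligase gene, was at 0.43 ± 0.08 in muscle, with 0.00723 adjusted over the list alone and an adjusted p of 0.106 over all genes, while the 10 neighbours tested there had a median of 0.05 (camera adjusted p = 0.925).

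Imprinted genes outside the Prader-Willi domain did not move as a list. In brain 23 of 32 were positive, with a median of 0.06 and camera's direction down (adjusted p = 0.700). In muscle 22 of 32 were positive with a median of 0.05 (adjusted p = 0.368). Hypothalamic peptide genes had a median of 0.08 in brain with camera's direction down (adjusted p = 0.726), and muscle atrophy genes a median of 0.05 in muscle (adjusted p = 0.253). Glycolysis genes had medians of -0.01 in brain (adjusted p = 0.183) and 0.02 in muscle (adjusted p = 0.893), the latter with a mean of -0.02.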
